A study of Mus musculus with 2 samples.

How the data were processed

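The data are 2 RNA-seq libraries of sorted mouse bone marrow haematopoietic stem cells, 1 labelled Per2wt and 1 labelled Per2def. Groups were taken from the genotype label of each sample. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, and libraries were made with a kit that marks strand. The sort markers, the time of day of collection and the Per2 allele are not given in the sources used here. The deposited values are FPKM per gene (fragment counts set relative to transcript length and to the mapped fragments of the library), computed by the authors with Cufflinks, per the file headers and the submitters' processing notes. The same notes name CASAVA 1.8, TopHat, Bowtie2 and Cufflinks, and the builds GRCm38 and mm10. Versions of TopHat, Bowtie2 and Cufflinks, the gene annotation, read filters and the strand setting are not given in the sources used here. Because the strand setting is not known, reads of overlapping and antisense genes cannot be told apart with certainty. FPKM are relative to each library's own total, so a few very abundant rows move all others. Cufflinks shares multiply mapping reads among copies, so values of near-identical genes can trade places between libraries.

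Each file held 24487 rows and 23995 gene symbols. A total of 9 rows carried the Cufflinks flag for too much data, hold 0 without an estimate, and were left out (Arhgap21, Cmss1, D130009I18Rik, Filip1l, Jarid2, Lars2, Peak1, Rn45s and Zc3h7a). A further 27 rows whose symbols had been turned into dates were left out because the gene cannot be named. Rows sharing a symbol (754 rows) were summed, which left 23961 symbols. Gene identifiers and coordinates were taken by symbol from GENCODE M21 (GRCm38), which placed 22660 of them.

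No statistical test fits 1 library per genotype, so values are described. For each gene the difference was log2(FPKM + 1) in Per2def minus log2(FPKM + 1) in Per2wt. Counts cover the 11121 genes at 1 FPKM or more in at least 1 library and a 2-fold threshold on that scale. A total of 43 gene lists were fixed before the data were examined, along with the rule for named genes, the main measures and the alternatives. They cover the clock, stem and progenitor cell markers, blood, endothelial and stromal cell types, cell cycle, stress, signalling, metabolism, ribosomes, histones, X and Y transcripts and housekeeping genes. For each list with at least 5 measured genes the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and described as apart when outside the middle 95% of them. Of 874 different symbols in the lists, 850 were found in the files, 5 of them by an older name in the RefSeq gene table (Adgre1, Epb42, Jchain, Tigar and Wfdc21). This lookup of older names was added after the values had been seen. Genes within 10 Mb of Per2 were treated as a further list.

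Genes were named by a fixed rule. It takes Per2 and every clock gene, the 12 highest and 12 lowest differences among genes at 5 FPKM or more in at least 1 library other than small or predicted RNAs and antigen receptor segments, up to 4 genes of the largest absolute difference from each list described, the 5 most abundant genes of each list of other cell types, and Xist with the Y-linked genes. Ms4a3, Cebpa, Cebpe, Gfi1, Kit, Procr, Ide, Fgfbp3, Btaf1 and Nnt fall outside the rule and were chosen after their values were seen. So were the sets of primary granule, secondary granule and late neutrophil genes. One clock gene that the rule names is not reported here.

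Relative depth was read from genes above 0 and under 0.5 FPKM in both libraries. A single read in each library gives an FPKM ratio that is the inverse of the depth ratio, and the most common ratio among these genes was taken in bins of 0.005 on the log2 scale. Of the 3232 such genes 255 fell in the most common bin and 171 in the next. This gives no absolute depth, so no counting interval can be attached to an FPKM value, and low values carry the most counting error.

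Alternatives were other scalings of the libraries (median of ratios, a fixed total, upper quartile), pseudocounts of 0.1 and 0.5 FPKM, no filter and a floor of 5 FPKM, the highest row per symbol, leaving out small and predicted RNAs, fold thresholds of 1.5 and 4, the mean in place of the median, and 10 bins. Added after seeing the data were the mean without small and predicted RNAs, the erythroid list without globins, the neutrophil list without 8 granule genes and the multipotent progenitor list without the 4 genes it shares with the neutrophil list.

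The procedures were tested on simulated data made from the 11121 genes of this comparison. Of 200 genes given a 4-fold change, 199 came out in the right direction and 99.5% passed the 2-fold threshold. These genes were drawn at a mean of 5 FPKM or more and without small or predicted RNAs. A 4-fold change there passes 2-fold nearly by construction, so recovery among low genes and small RNAs was not tested. Of 100 simulated lists of 20 genes with no shift 3% fell outside the percentiles, against 63% with a shift of 0.1 and 100% with a shift of 0.3 on the log2 scale. For lists of 8 genes these shares were 6%, 28% and 96%. Differences were first shuffled among genes of like expression, so these shares do not cover lists whose members vary together. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.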

Results

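RNA was sequenced from haematopoietic stem cells, the cells that renew all blood lineages, sorted from the bone marrow of untreated C57BL/6 mice. One library is labelled wild-type (Per2wt) and 1 is labelled Per2-deficient (Per2def), and how many animals gave each library is not stated in the labels. The sort markers are not given, so the libraries may hold progenitors beside stem cells. Flt3, of the multipotent progenitor list, stood at 48.8 FPKM in Per2wt and 51.4 FPKM in Per2def. Of the stem cell list, Kit stood at 42.7 and 43.6 FPKM and Procr at 2.61 and 3.02 FPKM. Slamf1, Fgd5 and Hoxb5, also on that list, were not among its 42 genes measured at 1 FPKM or more in either library. The share of stem cells in each library is therefore unknown. Per2 encodes a repressor of the circadian clock, and the comparison asks how gene expression in these cells differs between the genotypes. The deposited values are FPKM per gene. With 1 library per genotype there is no replicate check, no p-value, no standard error and no test, so each difference compares these libraries and not the genotypes. Differences are given as log2 of (FPKM + 1), Per2def minus Per2wt, a scale that understates the change of low genes. Folds, where printed, are plain ratios of FPKM. The Per2wt library listed 10673 genes at 1 FPKM or more and the Per2def library 10908. The files give no read totals, so absolute depth is unknown and no interval or detection floor can be set. Among 3232 low genes the most common ratio of Per2def to Per2wt FPKM was 0.805, shared by 255 genes, which is what a Per2def library 1.24 times as deep would give. One row named for a small RNA, Mir6236, took 71.3% of all FPKM in Per2wt and 71.5% in Per2def. FPKM are set relative to length, so a very short row can take a far larger share of FPKM than of reads. That share is therefore not a share of the RNA.

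Per2 RNA was higher in the library labelled Per2def, the opposite of what loss of the transcript would give. The gene (ENSMUSG00000055866.9, chromosome 1, 91415982 to 91459324, GRCm38) stood at 1.96 FPKM in the library labelled Per2wt and at 6.16 FPKM in the library labelled Per2def, 3.13-fold higher (log2 difference 1.27). The labels do not name the allele, and an allele that removes part of a gene can still make RNA from the rest, so this value neither supports nor excludes the labels. Every direction below is between the libraries as labelled. Xist, the RNA that silences an X chromosome in female cells, was at 61.5 FPKM in Per2wt and 67.5 FPKM in Per2def. The Y-linked Ddx3y stood at 0.00491 and 0.0119 FPKM, and Eif2s3y, Kdm5d, Uty, Usp9y, Zfy1 and Zfy2 were listed at 0 in both.

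Other clock genes at 1 FPKM or more differed less than Per2 on the log2(FPKM + 1) scale. Of 16 measured members of the core clock list, 13 were higher in the library labelled Per2def, with a median log2 difference of 0.13, at the 92.4th percentile of random lists of the same size matched on expression. Per1, the closest relative of Per2, went from 4.87 to 6.65 FPKM (0.38), and the output factor Tef from 3.25 to 4.34 FPKM (0.33). Timeless, which also acts at replication forks, went from 12.8 to 16.6 FPKM (0.35). Arntl, which encodes the activator BMAL1, was lower, at 3.35 against 2.09 FPKM (−0.49), as were the kinase gene Csnk1e (−0.52) and Hlf (−0.34), a clock output factor that is also a stem cell regulator. Nr1d1 (0.19), Nr1d2 (0.22), Cry2 (0.20), Nfil3 (0.12), Dbp (0.08), Per3 (0.04), Csnk1d (0.03) and Cry1 (0.01) differed little. Clock, at 0.624 and 0.626 FPKM, and Npas2, Bhlhe40 and Ciart were under 1 FPKM in both libraries. The 70 genes within 10 Mb of Per2 had a median difference of 0.08, at the 87.7th percentile, and 51 of them were higher in the library labelled Per2def.

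**Figure D1:**
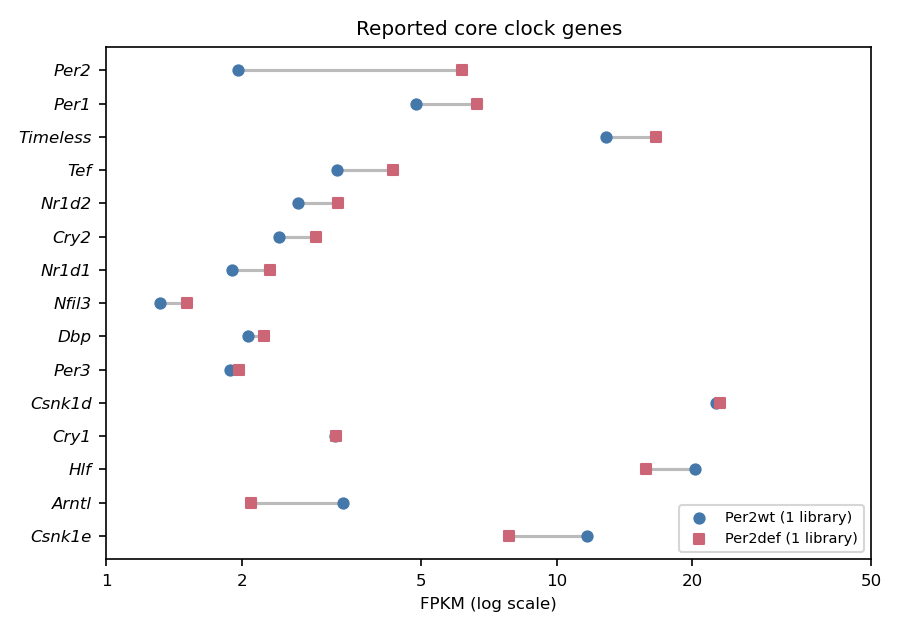
FPKM of the clock genes reported here in the library labelled Per2wt and the library labelled Per2def, 1 value per gene and library, no error because each genotype has 1 library. The x axis is logarithmic, and Per2 stands at 1.96 against 6.16 FPKM.

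Most genes were alike in the 2 libraries, and most 2-fold differences lay in rows named as small or predicted RNAs. Of 11121 genes at 1 FPKM or more in either library, 139 (1.25%) were at least 2-fold higher in the library labelled Per2def and 111 (0.998%) at least 2-fold lower. Small or predicted RNAs made up 112 of the first group and 94 of the second, leaving 27 and 17 other genes. That class goes by symbol alone, so it also takes in Wfdc21, whose row carries an older name. A short row reaches a high FPKM from few reads, so the differences of small RNAs are uncertain. With a pseudocount of 0.1 FPKM, 217 genes were at least 2-fold higher and 137 at least 2-fold lower. Of the 139, 77 were listed at 0 in the library labelled Per2wt, and of the 111, 65 in the other. The correlation of log2(FPKM + 1) across genes was 0.862 (Pearson), where genes are not independent replicates. The median difference of all these genes was 0.05, and 6895 of them were higher in the library labelled Per2def and 4226 lower, so that more than an even share of a list is higher without standing apart. Leaving out small and predicted RNAs, the middle 95% of differences ran from −0.39 to 0.52 for genes at 1 to 5 FPKM and from −0.34 to 0.31 for genes at 20 to 100 FPKM.

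**Figure D2:**
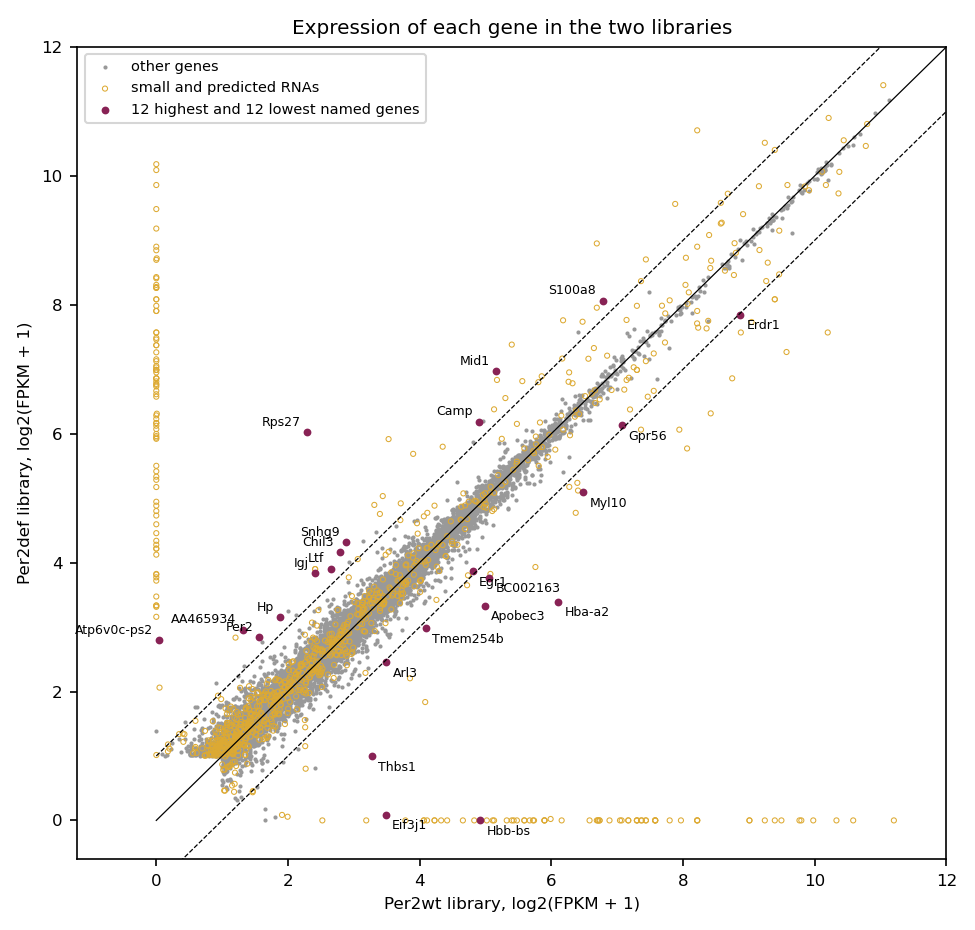
Each point is a gene at 1 FPKM or more in either library, with log2(FPKM + 1) in the Per2wt library on the x axis and in the Per2def library on the y axis. Dashed lines mark 2-fold differences, open circles are small and predicted RNAs, filled circles are the 12 highest and 12 lowest named genes, and 4 genes lie outside the axes.

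Genes of neutrophils and their granules were higher in the library labelled Per2def, with the highest median of the lists with at least 5 measured genes. Of 24 measured members 21 were higher, 10 of them at least 2-fold, and the list median of 0.64 was above all random lists (percentile 100). The alarmin subunits S100a8, at 109 against 266 FPKM (1.28), and S100a9, at 83.6 against 191 FPKM (1.18), were the most abundant of them beside Mpo, the myeloperoxidase gene, at 143 against 181 FPKM (0.34). The 8 secondary granule and S100 genes had a median of 1.25 (range 0.80 to 1.38), with the antimicrobial peptide gene Camp at 28.9 against 72.0 FPKM (1.29), Ngp at 30.3 against 72.5 FPKM (1.23), lactoferrin gene Ltf at 5.28 against 14.01 FPKM (1.26) and the chitinase-like Chil3 at 5.92 against 17.0 FPKM (1.38). Wfdc21, found under an older name, was at 1.30 against 6.14 FPKM (1.63). The set of 5 primary granule genes had a median of 0.65, and its range of 0.34 to 1.25 overlapped that of the secondary set. The top of that range is Ms4a3, at 3.02 against 8.55 FPKM (1.25), which encodes a membrane protein and not a granule protein. Elane, neutrophil elastase, was at 27.1 against 57.5 FPKM (1.06), Ctsg at 35.9 against 56.98 FPKM (0.65) and Prtn3 at 48.2 against 65.9 FPKM (0.44). A set of 8 late neutrophil genes, chosen after the values were seen, had a median of 0.044 (range −1.66 to 0.38). Among them Retnlg, a gene of mature neutrophils, went the other way, from 2.16 FPKM in Per2wt to being listed at 0 in Per2def. Hp, which encodes haptoglobin and is in no list, was 2.97-fold higher, at 2.67 against 7.93 FPKM. The multipotent progenitor list, which shares 4 genes with the neutrophil list, had a median of 0.13 over 19 genes, at the 99.5th percentile, led by Elane, Ctsg, the cytokine receptor subunit Csf2rb (0.52) and Cd48 (0.47), and was no longer apart with a floor of 5 FPKM. That call rested on the shared genes, since without them the median was 0.045, inside the random range, with Cebpa, a regulator of granulocyte commitment, lower (−0.35).

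Erythroid genes split. Of 22 measured members 16 were higher in the library labelled Per2def (median 0.39, percentile 100), while the globins were lower. The carbonic anhydrase genes Car1, at 177 against 294 FPKM (0.72), and Car2, at 152 against 196 FPKM (0.37), the blood group gene Rhag, at 5.41 against 9.82 FPKM (0.75), and the erythropoietin receptor gene Epor, at 7.82 against 11.9 FPKM (0.54), were higher. All globin rows summed to 437 FPKM in Per2wt and 214 FPKM in Per2def (−1.03), with Hba-a1 at 193 against 115 FPKM, Hba-a2 at 67.8 against 9.50 FPKM, Hbb-b1 at 75.7 against 48.7 FPKM and Hbb-bt at 71.0 against 41.2 FPKM. Hbb-bs was listed at 29.2 FPKM in Per2wt and close to 0 in Per2def. Globin copies share reads, so the split among them is uncertain. The mean of the erythroid list was −0.11, opposite in sign to its median, because of the globins. Without the globins the median was 0.43 over 17 genes, 16 of them higher. The exception was Alas2, which was lower like the globins, at 1.46 against 0.792 FPKM (−0.46).

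Lists of other cell types went different ways. T cell markers (7 measured, 6 higher, median 0.42, percentile 99.9) were led by Cd3g, at 0.266 against 1.41 FPKM, Thy1, at 1.45 against 3.02 FPKM, and the transcription factor gene Tcf7, at 1.22 against 2.40 FPKM. These stood near 1 FPKM, while the most abundant member, Lat, was at 8.75 against 9.26 FPKM (0.07). Cd8b1 was lower (−0.04). Natural killer and innate lymphoid markers (6 measured, 5 higher, median 0.36, percentile 99.7) included Zbtb16 at 1.26 against 2.70 FPKM and Id2 at 1.55 against 3.15 FPKM. MHC class II genes (9 measured, 6 higher, median 0.32, percentile 100) included the invariant chain gene Cd74 at 9.16 against 17.0 FPKM (0.83), whereas H2-DMa was lower (−0.39). The mast cell and basophil list (5 measured, 3 higher) had a median of 0.27 at the 98.6th percentile, with the basophil protease gene Mcpt8 at 1.37 against 3.70 FPKM, while its most abundant members were lower, Srgn at 199 against 186 FPKM (−0.10) and Gata2 at 22.5 against 18.6 FPKM (−0.27). Dendritic cell markers (7 measured, 6 higher) had a median of 0.20 at the 97.6th percentile, with Ly6d at 1.52 against 4.25 FPKM. The most abundant members of the dendritic list differed little, Flt3 at 48.8 against 51.4 FPKM (0.07) and Bst2, the lower gene, at 40.2 against 36.5 FPKM (−0.14). The mast cell and dendritic calls, and that of the natural killer list, were lost without a filter on low values. Monocyte and macrophage markers (8 measured, 6 higher, median 0.15) stayed inside the random range at the 91.1st percentile, although Ly6c2 was at 6.60 against 15.0 FPKM (1.08). Endothelial markers (9 measured, median 0.07) lay at the 56.3rd percentile, with Ly6c1 at 2.04 against 4.54 FPKM. Ly6c1 and Ly6c2 are near copies and share reads, which makes both values uncertain. Megakaryocyte and platelet genes went the other way, with 11 of 17 lower (median −0.11, percentile 0.15). Thbs1, which encodes the matrix protein thrombospondin, was 8.74-fold lower, at 8.70 against 0.996 FPKM (−2.28), and Selp (−0.34) and Itgb3 (−0.28) were lower by less, as was Pf4, the platelet chemokine gene, at 15.8 against 13.9 FPKM (−0.17). Lists with under 5 measured genes have values only. Of 4 measured plasma cell genes Igj, the joining chain of immunoglobulins, was at 4.32 against 13.3 FPKM (1.43) and Sdc1 was lower (−0.55). Of 4 B lineage genes Dntt was at 68.7 against 60.6 FPKM and Cd37 at 33.4 against 36.9 FPKM. The stromal list had 3 measured genes, with Runx2 at 11.9 against 11.6 FPKM, and the eosinophil list 1, Prg2, at 0.824 against 1.99 FPKM.

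**Figure D3:**
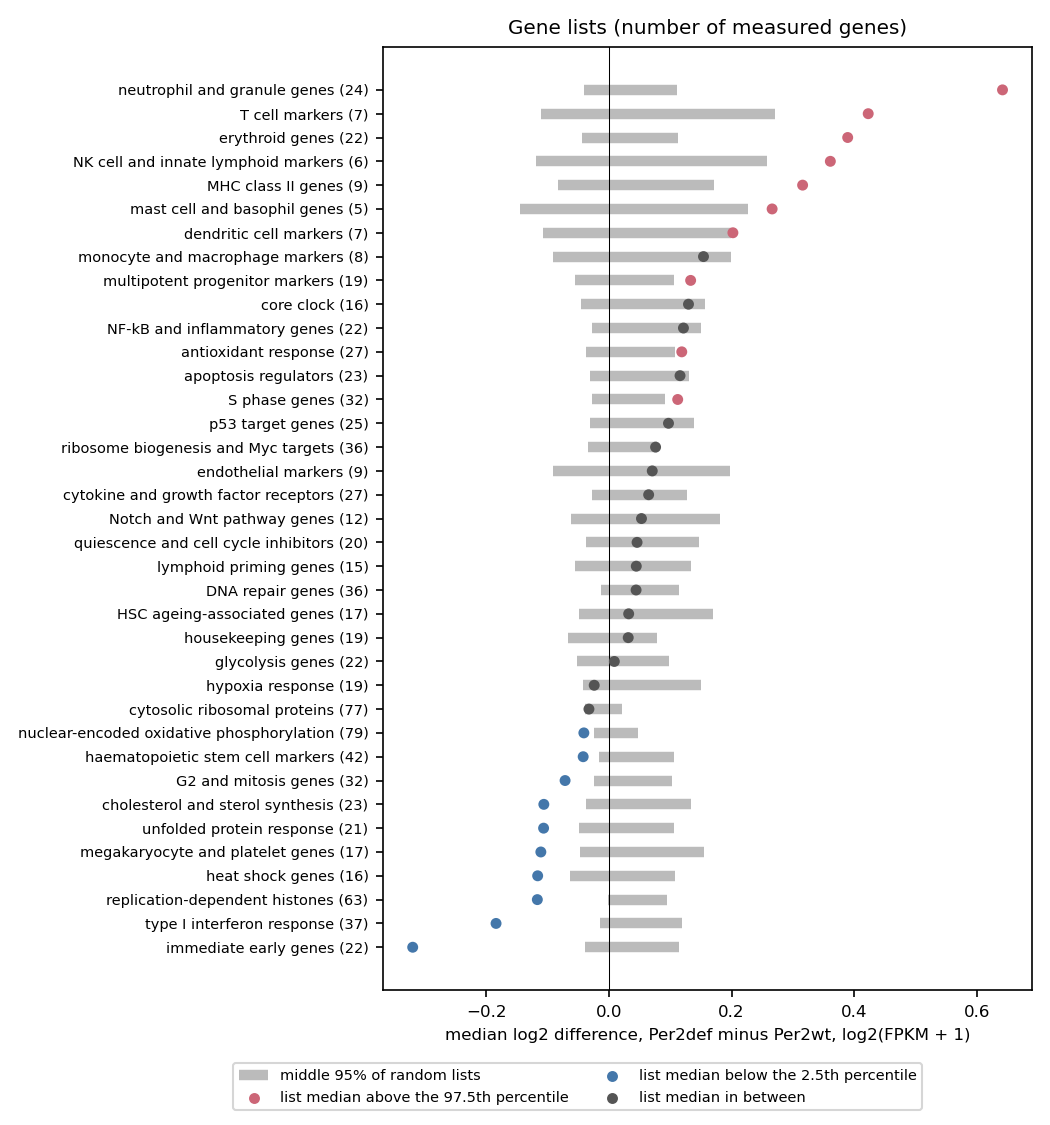
Median log2 difference (Per2def minus Per2wt, log2(FPKM + 1)) of each list with at least 5 measured genes, with the number of measured genes in brackets. Grey bars span the middle 95% of 10000 random lists matched on expression, and the neutrophil list lies farthest to the right at 0.64 and the immediate early list farthest to the left at −0.32.

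The median of the stem cell marker list was lower by a small amount in the library labelled Per2def. Of 42 measured markers 25 were lower, with a median of −0.04, at the 0.35th percentile. The widest differences were in Egr1 (−0.94), Txnip (−0.55), the channel gene Trpc6 (−0.52) and Thy1 (0.72). Egr1 is also in the immediate early list, and Cd48 (0.47) also in the multipotent progenitor list. Members went both ways, with Procr (0.15), Esam (0.15) and Kit (0.03) higher and Hlf (−0.34), Hoxa9 (−0.32) and Gata2 (−0.27) lower. The ageing-associated list (17 measured, median 0.03, percentile 29.0) was led by Ehd3, at 0.504 against 2.40 FPKM, with Fosb (−0.67) and Jun (−0.52) lower. Lymphoid priming genes (15 measured, median 0.04, percentile 52.6) included Ets1 at 2.48 against 4.01 FPKM. Cytokine and growth factor receptors (27 measured) had a median of 0.06 at the 59.5th percentile, with Epor and the interleukin 1 receptor gene Il1r1 (0.44) higher. The 12 measured Notch and Wnt pathway genes had a median of 0.05 at the 42.0th percentile.

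Genes that respond within minutes to stimulation were lower in the library labelled Per2def. Of 22 measured immediate early genes 20 were lower, with a median of −0.32, below all random lists (percentile 0). Egr1, a zinc finger factor gene, was at 26.9 against 13.6 FPKM (−0.94), the nuclear receptor gene Nr4a1 at 6.06 against 3.18 FPKM (−0.76), Fosb at 28.4 against 17.5 FPKM (−0.67) and Klf4 at 3.39 against 1.90 FPKM (−0.60). Heat shock genes were lower in 12 of 16 cases (median −0.12, percentile 0.19), chiefly Hspa1a, at 16.0 against 9.57 FPKM (−0.68), Hspa1b (−0.57) and Hsph1 (−0.40). Hspa1a and Hspa1b are near-identical and share reads, so the split between them is uncertain. The unfolded protein response list (21 measured, 12 lower, median −0.11, percentile 0.095) mixed Ern1 (−0.67) and Ppp1r15a (−0.47) with Asns, asparagine synthetase, which was higher (0.55).

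Interferon response genes were also lower. Of 37 measured members of the type I interferon list 30 were lower in the library labelled Per2def, with a median of −0.18 (percentile 0). Isg15, the ubiquitin-like modifier gene, was at 6.78 against 3.62 FPKM (−0.75), the antiviral Rsad2 at 2.05 against 0.861 FPKM (−0.71) and Ifi44 at 2.79 against 1.39 FPKM (−0.67). Xaf1 was the exception among the widest differences, at 3.36 against 8.13 FPKM (1.07). Apobec3, a restriction factor gene outside the list, was 3.39-fold lower, at 30.7 against 9.06 FPKM (−1.66). The inflammatory list around NF-kB (22 measured, median 0.12) lay at the 90.6th percentile, with the chemokine gene Ccl3 lower (−0.69) and Tnfaip2 higher (0.46).

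Cell cycle lists parted. S phase genes were higher in 27 of 32 cases (median 0.11, percentile 99.6), led by the replication factors Gins1, at 12.4 against 17.4 FPKM (0.46), and Cdt1, at 19.3 against 24.4 FPKM (0.32). Genes of G2 and mitosis were lower in 25 of 32 cases (median −0.07, percentile 0.02), led by the checkpoint kinase gene Bub1 (−0.30) and the motor gene Kif11 (−0.26). Replication-dependent histones were lower in 46 of 63 cases (median −0.12, percentile 0), with Hist1h4h at 21.3 against 12.6 FPKM (−0.71), Hist1h4d at 25.0 against 15.1 FPKM (−0.69) and Hist3h2ba at 2.78 against 0.883 FPKM (−1.01). Histone genes are near copies of each other and share reads, so single members are uncertain. These RNAs mostly lack poly(A) tails, and the libraries were made from poly(A) RNA, so their levels also follow how much untailed RNA each library took in. The quiescence list (20 measured, median 0.05, percentile 40.6), p53 targets (25 measured, median 0.10, percentile 84.0), DNA repair genes (36 measured, median 0.04, percentile 40.5) and apoptosis regulators (23 measured, median 0.12, percentile 94.7) stayed inside the random range. With a floor of 5 FPKM the quiescence median turned to −0.29 and the apoptosis median was 0.16, both then apart from random lists. Of the quiescence list, Egr1, Nr4a1, Klf2 and Btg2 are also in the immediate early list, so its call at that floor is not independent of that list. Of its other members at that floor, Cdkn1b (0.04), Cdkn2d (0.09), Rbl2 (0.20) and Ccng2 (0.22) were higher, and Txnip (−0.55) and Foxo3 (−0.24) lower.

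Metabolic lists differed by small amounts. Antioxidant genes were higher in 20 of 27 cases (median 0.12, percentile 98.6), led by the quinone reductase gene Nqo1, at 1.65 against 2.89 FPKM (0.55), and Gsta4 (0.51), but were not apart without a filter on low values. Sterol synthesis genes were lower in 16 of 23 cases (median −0.11, percentile 0.01), with Hmgcs1 at 5.09 against 4.11 FPKM (−0.25), while Lss was higher (0.42). Nuclear-encoded oxidative phosphorylation genes were lower in 51 of 79 cases (median −0.04, percentile 0.08). The antioxidant, sterol and oxidative phosphorylation calls were lost with the mean in place of the median, also when small and predicted RNAs were left out (0.12, −0.027 and −0.020). Glycolysis genes (22 measured, median 0.01, percentile 34.7), hypoxia genes (19 measured, median −0.02, percentile 5.35), ribosome biogenesis genes and Myc targets (36 measured, median 0.08, percentile 96.9), cytosolic ribosomal proteins (77 measured, median −0.03, percentile 6.83) and housekeeping genes (19 measured, median 0.03, percentile 76.2) lay inside the random range. The sign of the glycolysis and housekeeping medians turned under some alternatives, so neither has a direction. That also holds for the DNA repair, quiescence, ageing-associated, lymphoid priming and Notch and Wnt medians. No gene matched the list of mitochondrially encoded genes.

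In all, 37 lists had a percentile, of which 10 lay above and 10 below the middle 95% of random lists, where chance would put 1.85 outside. Random lists take genes to be unrelated, and members of 1 list vary together, so more than that number can fall outside with no effect of genotype. With the mean in place of the median, 2 of these 20 lists stayed apart, neutrophil and T cell, and 16 did when small and predicted RNAs were also left out.

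**Figure D4:**
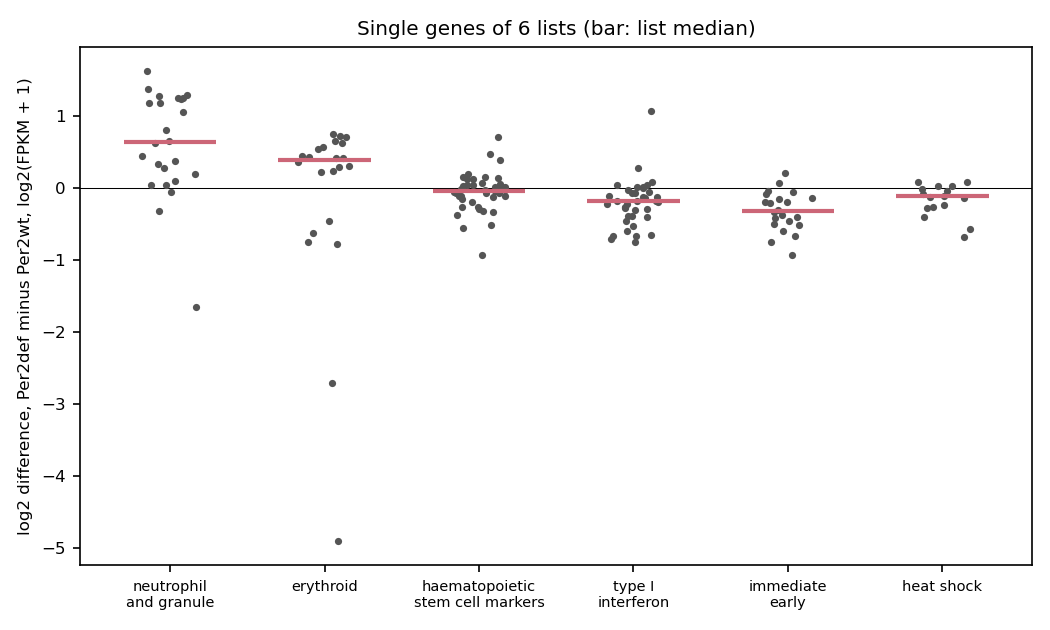
Log2 difference (Per2def minus Per2wt, log2(FPKM + 1)) of each measured gene of 6 lists, 1 point per gene, with a bar at the list median. The spread within a list shows how far its members move together, with globins far below 0 in the erythroid list.

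Other named genes with wide differences follow. Mid1 (chromosome X, 169685199 to 170005736, GRCm38), a ubiquitin ligase gene, was 3.56-fold higher in the library labelled Per2def, at 34.9 against 124 FPKM. AA465934 (1.49 against 6.78 FPKM) and the small RNA host gene Snhg9 (6.40 against 18.9 FPKM) were higher too. Erdr1, at 468 against 229 FPKM (−1.02), was lower. Mid1 and Erdr1 lie at the repeat-rich pseudoautosomal end of the X chromosome, which makes their mapping uncertain. So were the myosin light chain gene Myl10, at 88.5 against 33.1 FPKM (−1.39), the adhesion receptor gene Gpr56, at 134 against 69.3 FPKM (−0.94), and Arl3, at 10.3 against 4.48 FPKM (−1.04). Several of the widest differences sit in genes with a near-identical copy and are uncertain. Rps27 was at 3.89 against 64.1 FPKM (3.73), but with its copy Rps27rt the sum was 1184 against 1042 FPKM (−0.18). Eif3j1, at 10.2 against 0.0619 FPKM, came to 19.3 against 21.2 FPKM with Eif3j2 (0.13). Atp6v0c-ps2, at 0.0296 against 5.98 FPKM, came to 41.6 against 41.3 FPKM with Atp6v0c (−0.01), and BC002163, at 32.3 against 12.6 FPKM, to 43.8 against 35.4 FPKM with Ndufs5 (−0.30). Tmem254b and its copies summed to 16.6 against 6.90 FPKM (−1.16), so that difference was not one of division among them.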

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

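The mean without small and predicted RNAs, the erythroid list without globins, the neutrophil list without 8 granule genes and the multipotent progenitor list without the 4 shared genes were chosen after seeing the data, and the other alternatives were planned. Per2 was higher in the library labelled Per2def under every alternative run for it (log2 1.23 to 1.60). Of 1280 values of named genes under alternatives, 1266 kept their side of the 2-fold threshold, 14 newly passed it, and 0 of those past it turned. Genes with differences near 0 were not followed in their sign. The 20 lists apart from random kept their side under all 3 scalings, the pseudocount of 0.5 FPKM, the highest row per symbol and 10 bins. Each scaling multiplies a library by 1 factor, which shifts a list and its random lists nearly alike, so it could hardly change a call. The erythroid list without globins (0.43) and the neutrophil list without 8 granule genes (0.31) kept theirs too, and the multipotent progenitor list without the 4 genes it shares with the neutrophil list (0.045) was no longer apart. Genes at least 2-fold higher numbered 217 with a pseudocount of 0.1 FPKM (137 lower) and 27 without small and predicted RNAs (17 lower). At a threshold of 1.5-fold 290 were higher (189 lower), and at 4-fold 87 (77 lower). A smaller or larger threshold changes such a count by construction.

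List medians that moved across the percentiles were as follows, and the cause was not tested unless stated. With a pseudocount of 0.1 FPKM the dendritic list (0.22) was no longer apart. Without a filter on low values the dendritic (0.13), natural killer (0.10), mast cell (0) and antioxidant (0.082) lists were no longer apart, and apoptosis regulators (0.13) and cytosolic ribosomal proteins (−0.032) became so. With a floor of 5 FPKM the multipotent progenitor list (0.073) was no longer apart, and the quiescence list (−0.29) and apoptosis regulators (0.16) became so, with fewer genes in each. The quiescence list shares Egr1, Nr4a1, Klf2 and Btg2 with the immediate early list. At that floor 16 of the 20 lists apart still had enough genes and 15 kept their side, and the T cell, natural killer, dendritic and mast cell lists could not be assessed. Without small and predicted RNAs ribosome biogenesis genes (0.076) became apart, and with 10 bins cytosolic ribosomal proteins (−0.032).

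The mean in place of the median left 2 of the 20 lists apart, neutrophil and T cell. The means no longer apart were stem cell −0.057, multipotent progenitor 0.17, dendritic 0.36, MHC class II 0.18, natural killer 0.38, megakaryocyte −0.21, mast cell 0.26, S phase 0.13, G2 and mitosis −0.070, interferon −0.21, immediate early −0.32, heat shock −0.17, unfolded protein −0.067, antioxidant 0.12, oxidative phosphorylation −0.020, sterol −0.027 and histones −0.16. The erythroid mean turned to −0.11 because of the globins. Random lists hold small RNAs with very wide differences, which broadens the range of their means, and with these RNAs left out 16 of the 20 lists stayed apart. There the antioxidant (0.12), oxidative phosphorylation (−0.020) and sterol (−0.027) means were not apart, the erythroid mean was turned (−0.11), and monocyte (0.24), quiescence (−0.076) and genes near Per2 (0.12) became apart. Unknown absolute depth limits all of these most for genes near 1 FPKM. No paired analysis was possible because each genotype has 1 library.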

Other observations

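The 3 scalings were planned, while the bound set on them and the other tests in this part were chosen after the result they bear on was seen.

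Neutrophil granule genes were higher in the library labelled Per2def. The lowest list median under the 3 other scalings was 0.586. Each scaling multiplies a library by 1 factor, and the median difference of all genes was 0.05, so little change could arise. Scaling is argued against by this small shift of all genes rather than by the 3 runs. RNA or cells of mature neutrophils in the sort would raise late neutrophil genes as well, and the 8 late genes had a median of 0.044 (range −1.66 to 0.38), but 3 of them were under 1 FPKM, which leaves this open. A larger share of granulocyte-committed progenitors may account for it but was not tested independently, because the set of 5 primary granule genes (median 0.65) belongs to the pattern itself. The 8 secondary granule and S100 genes differed more (median 1.25), and progenitors were not told apart from immature neutrophils. Regulators of granulocyte commitment went both ways. Cebpa was lower (−0.35), while Gfi1 (0.28) and Cebpe (0.09), both members of the neutrophil list, were higher. With 1 library per genotype a different sort and an effect of the genotype cannot be told apart.

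Per2 RNA was higher in the library labelled Per2def. A shift of the whole region is argued against by the 70 genes within 10 Mb, whose median was 0.079. Another collection phase stays open, since Per3, Dbp, Nr1d1, Nr1d2, Tef and Ciart had a median of only 0.14 and a highest value of 0.33, while Per1 (0.38) and the antiphase gene Arntl (−0.49) lay on the sides that a phase difference would give. An allele that loses part of the protein but still makes RNA, or exchanged labels, may give the same value, which gene-level FPKM does not separate and which was not tested.

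Single genes with very wide differences fall into several kinds. For 4 genes with a near-identical copy, Rps27, Eif3j1, Atp6v0c-ps2 and BC002163, single differences of 1.29 to 3.73 in size shrank to at most 0.30 when summed with the copy, which is consistent with reads divided differently between copies. Division among copies stays open for most of the single differences of Hbb-bs and Hba-a2, as the beta and alpha sums differed by −0.96 and −1.07, but it is argued against as the whole cause, since the sum of all globins still differed by −1.03. Ide, at 19.9 against 10.8 FPKM, and Fgfbp3, at 2.47 against 1.42 FPKM, were 1.84-fold and 1.73-fold higher in Per2wt while Btaf1 between Fgfbp3 and Ide on chromosome 19 differed by −0.05, and a copy number difference known among C57BL/6 mice is a candidate explanation. Nnt, which carries a deletion in C57BL/6J mice, was 1.85-fold higher in Per2def (6.49 against 12.0 FPKM), and whether the libraries come from different C57BL/6 substrains cannot be told apart from a genotype difference with gene-level values.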
